A study of Homo sapiens with 27 samples.

How the data were processed

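RNA was sequenced from 27 cultures of human EA.hy926 cells, a hybrid endothelial line made by fusing umbilical vein endothelial cells with the lung carcinoma line A549. The cultures fell into 7 groups. Control cells had no exposure, and the other groups met mesenchymal stromal cells (MSCs) of the hTERT-immortalised adipose line ASC52telo, or their products, for 48 h. Young MSCs were untreated. Senescent MSCs had received mitomycin C, a DNA crosslinker, at 1.5 µg/mL for 18 h and were then kept for 10 days, per the labels' protocols. Exposure was by decellularised extracellular matrix (ECM; 0.5% Triton X-100 and 20 mM NH4OH for 5 min), by conditioned medium (CM) mixed 1:1 with culture medium, or by direct co-culture at 1 MSC per endothelial cell. Each group had 4 libraries except senescent co-culture, which had 3, numbered 2 to 4. Replicate numbers came from the labels. The labels name 1 sequencing run for all 27 libraries. They do not say whether same-numbered cultures were grown in parallel, whether replicates came from separate cultures, or whether endothelial cells were separated from MSCs after co-culture, so p-values measure the spread between these libraries, which may be technical. The extraction protocol in the labels names MSCs as the source of RNA, while the cell type label names endothelial cells; the libraries are described here by the cell type label.

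Libraries were made from poly(A) RNA with a strand-marking kit, per the labels' protocols. Reads were aligned with HISAT2 2.2.1 to GRCh38 (hg38) and counted with featureCounts 2.0.1, per the submitters' processing notes. The strand setting used in counting and the annotation release are not given in the sources used here. Values of antisense and overlapping genes are therefore uncertain, as are those of genes with near-identical copies, among them AKR1C1, IFITM1, KRT8, KRT18 and the histone genes. The deposited table holds whole-number counts per gene, not normalised, for 60648 gene entries. The 44 entries for Y copies of pseudoautosomal genes, with 109832 counts over all libraries, were left out, and 60604 were used. A gene name table gave symbols for 60462 of them, and the GENCODE 29 annotation of GRCh38 gave positions and biotypes for 58336. No entry without a gene was present, and 0 columns belonged to other samples. Total counts per library ran from 66320519 to 111512357. No pair of libraries of a group agreed within sampling noise: the lowest chi-square per degree of freedom between 2 libraries of a group was 24.9.

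Genes were tested with edgeR 4.0.16 (quasi-likelihood F-test, 2-sided) on the deposited counts, after filterByExpr with a minimum of 10 counts and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. Unless another tool is named, every adjusted p of a gene is from that test. Control, ECM and CM groups were fitted together (20 libraries, 18714 genes), control and co-culture groups together (11 libraries, 17955 genes), and all 27 libraries together (19428 genes) where effects in co-culture were compared with those of another mode. There were 13 comparisons. Levels are CPM, counts relative to the library total, scaled by TMM over all libraries, with the SD between replicates, except that list shares and single-library levels of COL1A1, TERT, THY1, POSTN and PECAM1 are relative to the library total without TMM unless stated, and errors of log2 fold changes are standard errors. Gene symbols are those of the name table, and identifiers are given as deposited.

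The 28 gene lists were fixed before the data were examined. They cover endothelial identity, stromal cell identity, adipocyte lineage, epithelial identity, haematopoietic identity, smooth muscle and contractile genes, p53 targets, senescence-associated secretory factors, cell cycle, NF-kB and endothelial activation, interferon response, TGF-beta response and mesenchymal transition, YAP targets, angiogenic sprouting, Notch pathway, basement membrane, integrins and focal adhesion, hypoxia and glycolysis, cholesterol biosynthesis, integrated stress response, unfolded protein response, NRF2 and oxidative stress, ribosomal proteins, the mitochondrial genome, nuclear oxidative phosphorylation, immediate early genes, replication-dependent histones, and vasoactive and coagulation genes. Some genes belong to more than 1 list; COL1A1, for example, is in the stromal and TGF-beta lists. Lists were tested against all other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 28 lists of a comparison, and again with an estimated correlation and with fry, which tests whether a list's genes move one way without comparing them with other genes. An adjusted p of a list is from camera with the preset correlation unless stated.

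Genes were named by a rule fixed at the same time. Among protein-coding genes past the threshold, with a mean of at least 5 CPM in 1 of the groups and no overlap between the libraries of the groups, it takes the 8 largest rises and 8 largest falls in each comparison of senescent with young MSCs, and 5 and 5 elsewhere. It adds up to 3 members of each list past the threshold, or 2 elsewhere. The genes discussed are drawn from that set. Genes of the Y chromosome and XIST were left out of it.

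The libraries numbered 1 stood apart from the others in several measures, given with the results. After this was seen, every comparison was therefore also made on replicates 2 to 4 only, with the same tests, lists and naming rule. The fits then held 15 libraries and 18015 genes, 9 libraries and 17729 genes, or 21 libraries and 18492 genes. Those values were chosen after seeing the data and are named as replicates 2 to 4 in the paragraphs that print them.

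Whether equal replicate numbers pair libraries was checked by correlating, across genes, the deviations of same-numbered libraries from their group means. With all replicates every pair lay above 0.1 for senescent against young ECM (0.25 to 0.94), for ECM against control (0.61 to 0.85 with young and 0.21 to 0.84 with senescent MSCs) and for CM against control (0.4 to 0.86 and 0.57 to 0.82). In replicates 2 to 4 the same held for young ECM, young CM, senescent CM and young co-culture against control. For these comparisons the value with the replicate number as a block is given where it changes the result.

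Alternatives fixed at the same time were size factors of the DESeq2 type, scaling on the endothelial list alone in co-culture, no filter beyond 1 count, a minimum of 50 counts, other sets of libraries in the fit, the replicate block, DESeq2 1.42.0 (Wald test), and leaving out each library in turn. The analysis ran in R 4.3.3 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The tests were first run on simulated counts drawn from the real means and library sizes, with 200 genes changed, 100 of them 2-fold and 100 of them 4-fold. With all replicates, 24% of the 2-fold and 80% of the 4-fold changes were recovered for senescent against young ECM (18396 genes), 0% and 30% for senescent against young co-culture (17767 genes), 58% and 94% for ECM against CM (18366 genes), and 4% and 40% for the difference of senescence effects between co-culture and CM (19130 genes). In replicates 2 to 4 these shares were 48% and 93% (17780 genes), 65% and 94% (17470 genes), 79% and 100% (17767 genes), and 21% and 79% (18164 genes). A simulated list ranked 1 in each of these runs. Genes were drawn independently in them, so they do not test lists of correlated genes or differences shared by the libraries of a replicate number.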

Results

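Gene expression was measured by RNA sequencing in EA.hy926 endothelial cells kept alone or exposed for 48 h to young or mitomycin-treated senescent adipose MSCs, by way of their matrix, their medium or direct contact. The design asks what each way of exposure does to endothelial cells, and whether MSC senescence changes it. There were 4 libraries in each of 6 groups and 3 in senescent co-culture.

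Markers of stromal cells separated the libraries in a way that the groups do not. COL1A1 (ENSG00000108821), the main chain of collagen I, stood at 4120 CPM in control replicate 1, at 1870 and 2190 CPM in replicate 1 of young and senescent ECM, and at 4340 and 5000 CPM in replicate 1 of young and senescent CM. In the 15 other libraries of those groups it lay between 4.64 and 10.1 CPM. TERT, the telomerase gene carried by the immortalised MSC line, followed the same division, with 647 to 1220 CPM in those 5 libraries and 1.26 to 2.16 CPM in the others. The stromal identity list took 0.913 to 1.48% of the counts of those 5 libraries and 0.0634 to 0.215% of the others. The co-culture libraries held less of these transcripts: COL1A1 was at 50.4 to 77 CPM in young co-culture replicates 2 to 4 and at 126 to 181 CPM in senescent co-culture, and TERT at 6.33 to 8.55 and 3.21 to 4.82 CPM. Young co-culture replicate 1 stood apart in another way. Its ribosomal protein list took 16.9% of counts against 3.75 to 5.77% in replicates 2 to 4, and its TMM factor was 0.459 against 1.059 to 1.074. PECAM1, an endothelial adhesion receptor, was at 323 CPM against 1280 to 1370, and COL1A1 was at 13.9 CPM. All these levels are without TMM scaling. With it, PECAM1 was at 704 CPM against 1204 to 1278 and COL1A1 at 30.2 CPM. The 1st principal component of all 27 libraries held 48.2% of the variance, and the next ones 21.9% and 7.74%. The common biological coefficient of variation was 0.527 over the control, ECM and CM groups with all replicates and 0.216 with replicates 2 to 4.

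**Figure D1:**
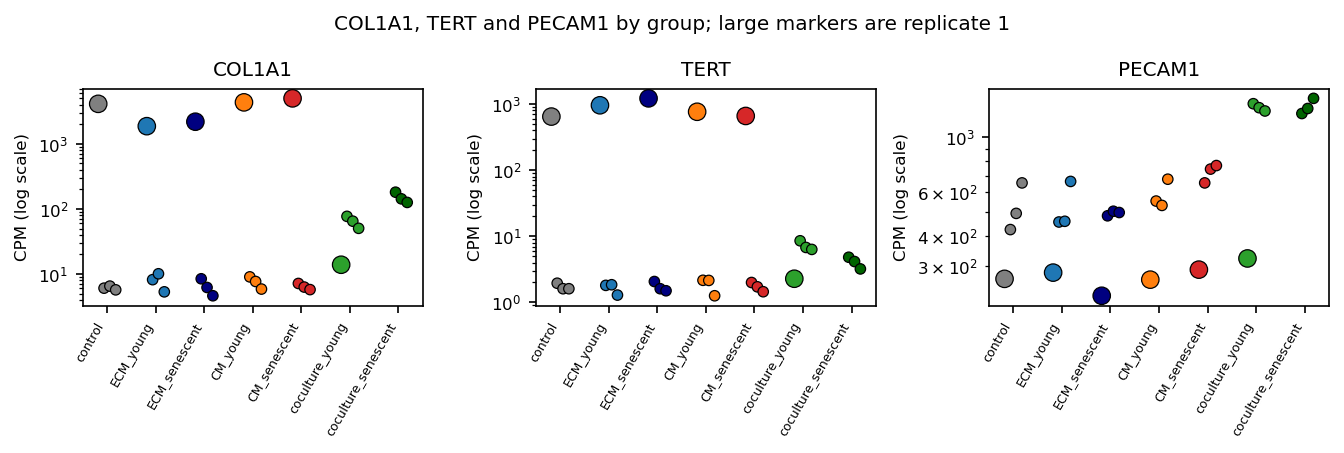
Level (CPM) of COL1A1, TERT and PECAM1 (log scales, without TMM scaling) in each library, by group, with replicate 1 of a group drawn as the large marker. COL1A1 lies between 1870 and 5000 CPM in replicate 1 of the control, ECM and CM groups and between 4.64 and 10.1 CPM in their other libraries.

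In co-culture with senescent MSCs, the secretory factor and stromal lists were higher than with young MSCs, and the interferon list was lower, in replicates 2 to 4. IL1B, the cytokine interleukin-1 beta, rose from 2.37 ± 0.43 to 12.7 ± 2.99 CPM (SD, n = 3 and 3; log2 fold change 2.43 ± 0.21, adjusted p = 0.00056). EREG, an EGF receptor ligand, rose by 2.98 ± 0.22 (adjusted p = 0.000409) and MMP3, a matrix protease, by 2.73 ± 0.28 (adjusted p = 0.000958), both from under 1 CPM. CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, fell from 12.7 ± 0.86 to 1.67 ± 0.44 CPM (log2 fold change −2.93 ± 0.27, adjusted p = 0.000799). OAS2, an antiviral enzyme gene of chromosome 12, fell from 68.3 ± 11.9 to 33.8 ± 3.55 CPM (−1.01 ± 0.17, adjusted p = 0.0255).

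The secretory factor list had 38 members measured in these replicates 2 to 4, of which 7 rose and 0 fell (19 and 1 adjusted over the list alone), with a median log2 fold change of 0.51 (adjusted p = 6.1e-31, and 0.0179 with an estimated correlation). In the stromal list 7 of 34 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.50, adjusted p = 1.6e-26, and 0.0368 with an estimated correlation), while its share of counts overlapped, at 0.308 to 0.319% with senescent and 0.262 to 0.36% with young MSCs. Its members included COL1A1 at 1.22 ± 0.18 (adjusted p = 0.0109), COL3A1 at 1.69 ± 0.21 (adjusted p = 0.00429), and LRRC15, a fibroblast surface protein, at 2.5 ± 0.30 (adjusted p = 0.00341). NOTCH3, a Notch receptor of mural cells, rose by 2.29 ± 0.22 to 3.34 ± 0.37 CPM, and MEDAG, a gene of adipocyte differentiation, by 3.07 ± 0.26 to 5.42 ± 1.25 CPM. TERT, which marks the MSC line, went the other way in mean level in these libraries, as given above. In the interferon list 0 of 39 rose and 4 fell (0 and 20 adjusted over the list alone; median −0.53, adjusted p = 2.06e-35, and 0.0368 with an estimated correlation). These were MX2 at −1.92 ± 0.23, XAF1 at −1.09 ± 0.18, OAS2, and IFITM1 at −1.40 ± 0.24, the last of which has near-identical copies. The cholesterol list was lower with 0 of 24 genes past the threshold (0 rises and 5 falls adjusted over the list alone; median −0.28, adjusted p = 1.06e-11, and adjusted p = 0.0654 with an estimated correlation). Basement membrane genes had 2 rises and 0 falls of 23 with a median of 0.05 (adjusted p = 0.000978, and adjusted p = 0.791 with an estimated correlation), among them NID2, nidogen-2, at 1.49 ± 0.24.

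In these replicates 2 to 4, 70 genes changed between senescent and young co-culture, 56 higher and 14 lower, at an adjusted p under 0.05. Scaling on the endothelial list gave 29 genes, 21 higher and 8 lower. The count was 25 without young replicate 2 or senescent replicate 2, 39 without young replicate 3, 28 without senescent replicate 3 and 26 without young replicate 4. With all replicates edgeR called 0 genes, with 566 at an unadjusted p under 0.05, DESeq2 called 4 (1 higher, 3 lower), and edgeR called 1 gene without young replicate 1. The ribosomal and interferon lists then had medians of −1.66 and −0.51 (adjusted p = 3.74e-16 and 2.66e-07). With an estimated correlation the adjusted p was 0.693 and 0.308.

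**Figure D2:**
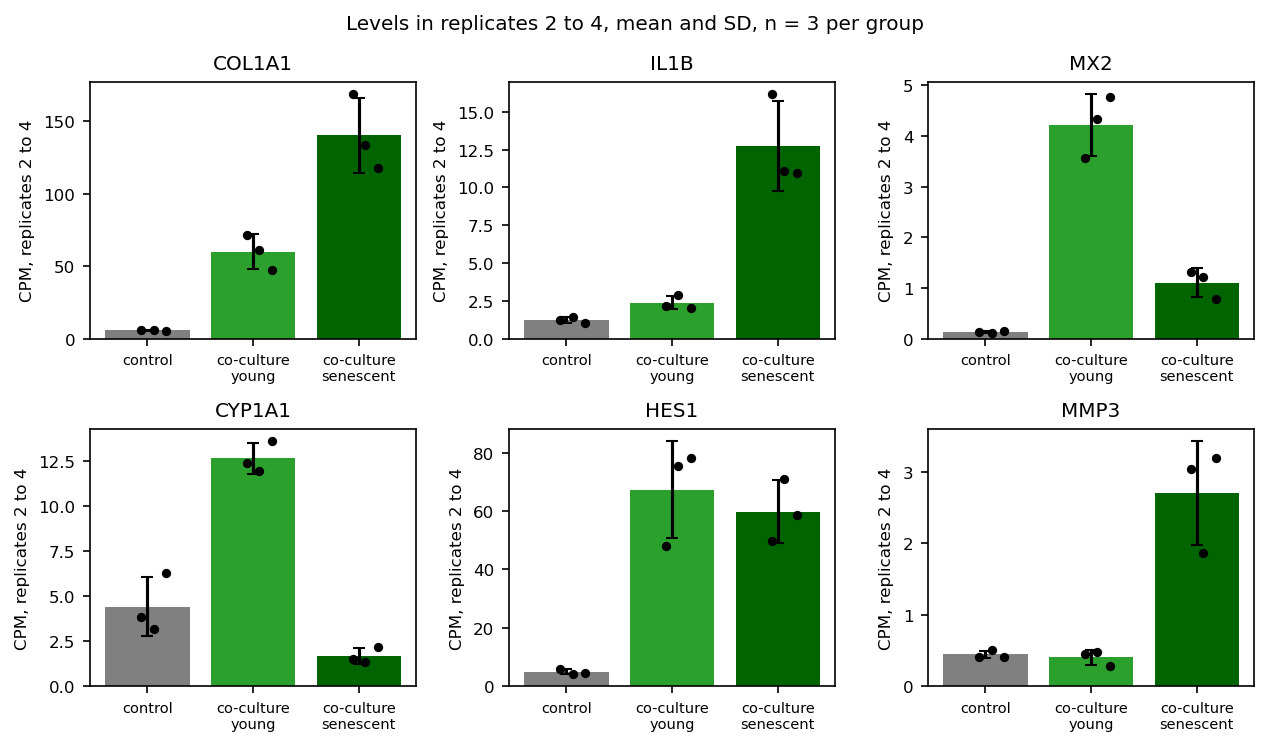
Level (CPM) of 6 genes in control and co-culture, replicates 2 to 4; bars are means, error bars SDs and points libraries, with n = 3 per group. IL1B averages 12.7 CPM with senescent and 2.37 CPM with young MSCs, and CYP1A1 1.67 and 12.7 CPM.

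With CM of senescent instead of young MSCs, 3 genes rose and 0 fell in replicates 2 to 4. NEDD9, a focal adhesion scaffold protein, rose from 5.21 ± 0.46 to 13.1 ± 0.20 CPM (SD, n = 3 and 3; log2 fold change 1.31 ± 0.15, adjusted p = 0.00593), and PCDH1, a protocadherin, from 46.8 ± 5.84 to 107 ± 6.42 CPM (1.18 ± 0.17, adjusted p = 0.0293). The other was MAF, a transcription factor gene outside the naming rule that was chosen after its values were seen (2.58 ± 0.34, adjusted p = 0.0123). Several lists moved as a whole with 0 members past the threshold over all genes. TGF-beta response genes had a median of 0.48 over 28 members (12 rises and 0 falls adjusted over the list alone; adjusted p = 4.64e-12, and adjusted p = 0.153 with an estimated correlation). Endothelial identity genes had a median of 0.45 over 31 members (adjusted p = 6.16e-09). Basement membrane genes had 0.47 over 23 (adjusted p = 5.2e-08). Both had an adjusted p of 0.36 with an estimated correlation. Ribosomal protein genes had a median of −0.44 (adjusted p = 6.16e-09, and adjusted p = 0.449 with an estimated correlation). Their share of counts was 7.31, 7.48 and 5.03% in young CM replicates 2 to 4, the last within senescent CM's 4.26 to 5.74%. The stromal list took 0.181 to 0.215% of counts in senescent CM replicates 2 to 4 and 0.0922 to 0.128% in young CM.

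The 3 genes of the CM comparison in replicates 2 to 4 became 1 without senescent replicate 2 or senescent replicate 4, and 0 without young replicate 3 or young replicate 4. DESeq2 called 46 genes in the same libraries, 35 higher and 11 lower. With all replicates edgeR called 0 genes, with 297 at an unadjusted p under 0.05, and DESeq2 called 1, while the TGF-beta list kept its direction (adjusted p = 1.48e-07, and adjusted p = 0.317 with an estimated correlation).

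On ECM of senescent instead of young MSCs, no gene passed the threshold in either set of libraries. SERPINB2, plasminogen activator inhibitor 2, was at 350.5 ± 43.1 CPM on young and 373 ± 76.4 CPM on senescent matrix in replicates 2 to 4 (SD, n = 3 and 3), and NOS3, endothelial nitric oxide synthase, at 1405 ± 459 and 1363 ± 458 CPM. Cell cycle genes had a median of 0.08 over 50 members in replicates 2 to 4, with 0 past the threshold (adjusted p = 0.00239, and adjusted p = 0.979 with an estimated correlation). Ribosomal protein genes had a median of −0.20 (adjusted p = 0.0207, and adjusted p = 0.979 with an estimated correlation). Their share of counts was 7.56% in young replicate 3 and 3.93 and 3.62% in young replicates 2 and 4. It was 4.11 to 4.98% in senescent replicates 2 to 4, so the fall rests on young replicate 3. With all replicates the ribosomal list gave an adjusted p of 0.0336, or 0.06 with the replicate number as a block, and 0.956 with an estimated correlation. Replicate 1 had ribosomal shares of 4.46% on young and 4.5% on senescent matrix, so young replicate 3 carries that result too. The counts of 0 came with 51 genes at an unadjusted p under 0.05 with all replicates and 141 in replicates 2 to 4, and DESeq2 also called 0 in both.

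Matrix of young MSCs was set against control to ask what decellularised ECM alone does. SERPINB2 rose in replicates 2 to 4 from 85.5 ± 15.7 to 350.5 ± 43.1 CPM (SD, n = 3 and 3; log2 fold change 2.04 ± 0.24, adjusted p = 0.000864). WNT16, a Wnt ligand, rose from 2.54 ± 0.92 to 10.4 ± 0.38 CPM (2.03 ± 0.33, adjusted p = 0.00982). STC1, the secreted hormone stanniocalcin-1, rose from 123 ± 16.4 to 458 ± 55.2 CPM (1.90 ± 0.29, adjusted p = 0.00673). In young ECM replicate 1, left out here, SERPINB2, WNT16 and STC1 stood at 56.2, 1.79 and 109 CPM. Those lay below the control means just given, but were not set against control replicate 1. KRT7, an epithelial keratin expressed by this line, fell from 1263 ± 164 to 513 ± 75.6 CPM (−1.30 ± 0.18, adjusted p = 0.00354). MYLK2, a myosin light chain kinase, fell by 1.64 ± 0.19 on the log2 scale (adjusted p = 0.000864). AMIGO2, an adhesion molecule, fell by 1.28 ± 0.14 (adjusted p = 0.000763), and EDN1, the vasoconstrictor endothelin-1, by 0.97 ± 0.14 (adjusted p = 0.00532).

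Among the lists in replicates 2 to 4, 7 of 40 secretory factor genes rose on young matrix and 0 fell (14 and 0 adjusted over the list alone; median 0.37, adjusted p = 8.78e-14, and adjusted p = 0.0966 with an estimated correlation). They included the EGF receptor ligand AREG at 1.59 ± 0.22 and the prostaglandin synthase PTGS2 at 1.60 ± 0.19. Immediate early genes had 3 rises and 1 fall of 21 (9 and 1 adjusted over the list alone; median 0.47, adjusted p = 3.87e-09, and adjusted p = 0.157 with an estimated correlation), with EGR1, a growth-factor-induced transcription factor, at 1.83 ± 0.33. Cell cycle genes had 0 rises and 1 fall of 50 (0 and 10 adjusted over the list alone; median −0.36, adjusted p = 4.19e-19, and adjusted p = 0.0966 with an estimated correlation); the fall was CDC20, a mitotic activator, at −0.66 ± 0.14. Epithelial genes had 0 rises and 1 fall of 11 (0 and 4 adjusted over the list alone; median −0.45, adjusted p = 4.1e-07, and 0.0333 with an estimated correlation). In the p53 target list 0 of 29 rose and 1 fell (0 and 1 adjusted over the list alone; median −0.19, adjusted p = 6.1e-06, and 0.0182 with an estimated correlation), the fall being BTG2, an antiproliferative gene, at −0.86 ± 0.17.

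The test on replicates 2 to 4 called 117 genes for young ECM against control, 83 higher and 34 lower, or 321 (228 and 93) with the replicate block. The count was 45 without ECM replicate 2, 65 without control replicate 3, 27 without control replicate 4 and 40 without ECM replicate 4. With all replicates 1 gene passed, TSC22D1 (ENSG00000102804.15, chromosome 13, 44432143 to 44577147 of GRCh38), a TGF-beta-stimulated gene that rose from 71.5 ± 4.12 to 108 ± 8.3 CPM (SD, n = 4 and 4; log2 fold change 0.59 ± 0.08, adjusted p = 0.016). With the replicate block 101 genes passed, 77 higher and 24 lower. Leaving out ECM replicate 1 gave 16 genes, and leaving out any 1 of the other 7 libraries gave 0. DESeq2 called 32 with all replicates.

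Matrix of senescent MSCs was set against control in the same way. SERPINB2 rose in replicates 2 to 4 by 2.13 ± 0.24 on the log2 scale to 373 ± 76.4 CPM (SD, n = 3; adjusted p = 0.00124). CCN3, a matricellular regulator of growth, rose by 1.90 ± 0.22 to 19.8 ± 3.81 CPM (adjusted p = 0.00124), and CXCL1, a neutrophil chemokine, by 1.64 ± 0.32 to 5.23 ± 0.48 CPM (adjusted p = 0.0431). MYLK2 fell by 1.58 ± 0.19 (adjusted p = 0.00124), KRT7 by 1.19 ± 0.18 (adjusted p = 0.00821) and EDN1 by 0.74 ± 0.14 (adjusted p = 0.0402). In senescent ECM replicate 1, left out here, MYLK2 was at 13.9 CPM and KRT7 at 917 CPM. The other senescent ECM libraries held 2.71 to 3.58 and 535 to 575 CPM. Of 40 secretory factor genes 4 rose and 0 fell (14 and 0 adjusted over the list alone; median 0.39, adjusted p = 1.2e-15, and adjusted p = 0.0846 with an estimated correlation). Epithelial genes had 0 rises and 1 fall of 11 (0 and 4 adjusted over the list alone; median −0.41, adjusted p = 1.99e-07, and 0.0251 with an estimated correlation). Cell cycle genes and p53 targets had medians of −0.28 and −0.20 with 0 past the threshold. Their adjusted p was 8.61e-14 and 6.38e-05, and 0.125 and 0.0251 with an estimated correlation. In all, 54 genes changed, 40 higher and 14 lower, and DESeq2 called 225. The edgeR count was 34 without control replicate 2, 20 without ECM replicate 2, 14 without ECM replicate 3, 12 without control replicate 4 and 25 without ECM replicate 4. With all replicates it was 0, with 584 at an unadjusted p under 0.05, or 123 (90 higher, 33 lower) with the replicate block, and DESeq2 called 32.

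CM of young MSCs set against control gave 0 genes past the threshold in both sets of libraries by edgeR, with 321 at an unadjusted p under 0.05 with all replicates and 846 in replicates 2 to 4. DESeq2 called 0 and 34. With the replicate block 6 genes passed in replicates 2 to 4, 5 higher and 1 lower, and leaving out 1 library gave 1 gene without control replicate 2, control replicate 4 or CM replicate 4 and 2 without control replicate 3. In those libraries KRT7 stood at 2237 ± 413 CPM against 1263 ± 164 CPM in control (SD, n = 3 and 3), and MMP1, interstitial collagenase, at 2296 ± 44.3 against 3895 ± 280 CPM, neither past the threshold. Their ribosomal protein genes had a median of 0.48 (adjusted p = 2.53e-11) and nuclear oxidative phosphorylation genes 0.35 (adjusted p = 2.83e-07). Both had an adjusted p of 0.811 with an estimated correlation.

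CM of senescent MSCs was set against control. TNFSF15, a cytokine made by endothelial cells, rose in replicates 2 to 4 from 5.44 ± 2.73 to 24.9 ± 1.85 CPM (SD, n = 3 and 3; log2 fold change 2.21 ± 0.26, adjusted p = 0.00106). SNAI1, a transcription factor of mesenchymal transition, rose from 16.8 ± 5.47 to 49.5 ± 6.07 CPM (1.56 ± 0.24, adjusted p = 0.00802). HES1 (ENSG00000114315.4, chromosome 3, 194136145 to 194138732 of GRCh38), a target of Notch, rose from 4.90 ± 0.85 to 16.9 ± 3.21 CPM (1.79 ± 0.31, adjusted p = 0.0152). EDN1 rose by 0.97 ± 0.14 (adjusted p = 0.00599) in the same libraries. SERPINB2 fell from 85.5 ± 15.7 to 17.6 ± 5.79 CPM (−2.27 ± 0.24, adjusted p = 0.000469). RELN, the secreted matrix protein reelin, fell from 9.89 ± 1.62 to 2.33 ± 1.07 CPM (−2.08 ± 0.29, adjusted p = 0.00435), and MMP1 from 3895 ± 280 to 1519 ± 254 CPM (−1.35 ± 0.15, adjusted p = 0.000469).

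TGF-beta response genes had 2 rises and 0 falls of 28 in replicates 2 to 4 of that comparison (7 and 1 adjusted over the list alone; median 0.32, adjusted p = 1.6e-10, and adjusted p = 0.118 with an estimated correlation). Angiogenic sprouting genes had 1 rise and 0 falls of 29 (8 and 0 adjusted over the list alone; median 0.46, adjusted p = 5.16e-12, and adjusted p = 0.145 with an estimated correlation). NRF2 genes had 0 rises and 2 falls of 24 (0 and 3 adjusted over the list alone; median −0.29, adjusted p = 4.36e-09, and 0.0483 with an estimated correlation), the falls being TXNRD1, thioredoxin reductase, at −0.90 ± 0.18 and SLC7A11, the cystine transporter, at −0.98 ± 0.21. Epithelial genes had 2 rises and 0 falls of 11 (4 and 0 adjusted over the list alone) and a test towards higher values (adjusted p = 0.00201, and adjusted p = 0.145 with an estimated correlation), while their median was −0.10 and their mean 0.10. The test called 91 genes, 55 higher and 36 lower, or 230 (137 and 93) with the replicate block, and DESeq2 called 261. The edgeR count was 54 without CM replicate 2, 42 without control replicate 3 or CM replicate 3, 24 without control replicate 4 and 22 without CM replicate 4. With all replicates it was 0, with 553 at an unadjusted p under 0.05, or 84 (59 higher, 25 lower) with the block, and 3 without CM replicate 1. DESeq2 called 38. The epithelial list then had an adjusted p of 0.00744, or 0.0505 with the block, and 0.122 with an estimated correlation.

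**Figure D3:**
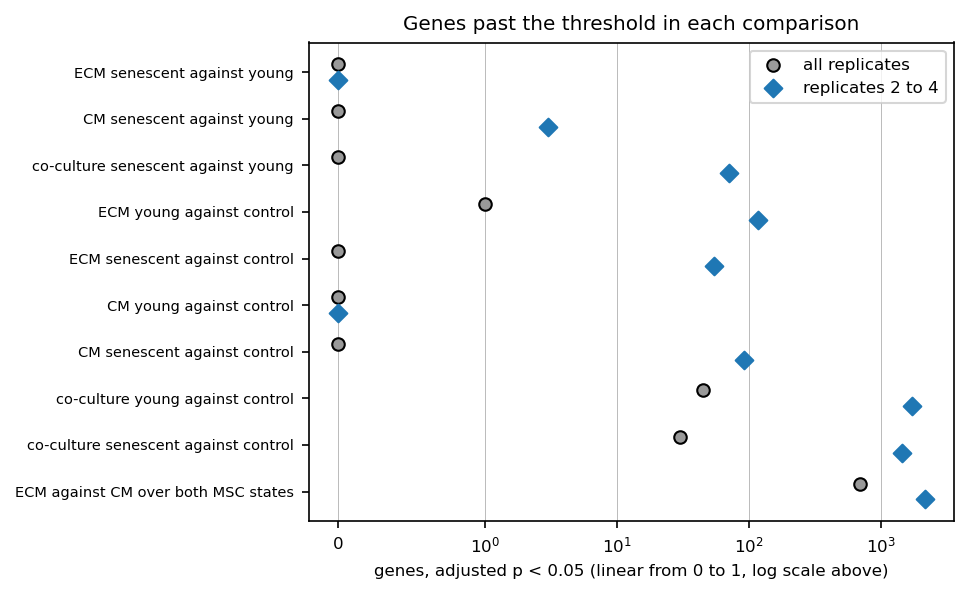
Number of genes at an adjusted p under 0.05 in each of 10 comparisons (axis linear from 0 to 1 and logarithmic above), with all replicates as circles and replicates 2 to 4 as diamonds. The counts for young co-culture against control are 45 and 1716.

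Co-culture with young MSCs set against control raised HES1 with all replicates by 3.01 ± 0.49 on the log2 scale (adjusted p = 0.0413) and EFNA1, the ligand ephrin-A1, by 2.48 ± 0.25 (adjusted p = 0.00943). ALDH1A1, a retinaldehyde dehydrogenase, rose by 2.41 ± 0.31 (adjusted p = 0.0182), and the interferon-induced OAS1 and IFI44L by 1.93 ± 0.30 and 1.84 ± 0.31. RELN fell by 3.65 ± 0.47 (adjusted p = 0.0182), the growth factor FGF1 by 2.58 ± 0.39 (adjusted p = 0.0337) and AOX1, an aldehyde oxidase, by 2.11 ± 0.24 (adjusted p = 0.00943). HES1 in replicates 2 to 4 was at 67.3 ± 16.6 CPM against 4.90 ± 0.85 in control (SD, n = 3 and 3), RELN at 0.69 ± 0.11 against 9.89 ± 1.62, MX2 at 4.22 ± 0.61 against 0.13 ± 0.02, and CDH5, the endothelial cadherin, at 705 ± 105 against 250.5 ± 54.1 (1.50 ± 0.18, adjusted p = 0.000398).

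All 28 lists are given for this comparison in replicates 2 to 4, beside the stromal share of 0.262 to 0.36% of counts in co-culture against 0.0832 to 0.137% in control. Interferon genes had 19 rises and 1 fall of 39 (34 and 1 adjusted over the list alone; median 0.79, adjusted p = 1.01e-33), with XAF1 at 3.79 ± 0.21. Stromal genes had 20 rises and 1 fall of 34 (28 and 2 adjusted over the list alone; median 1.29, adjusted p = 5.02e-29), with COL1A1 at 3.37 ± 0.19. Endothelial identity genes had 18 rises and 0 falls of 30 (21 and 0 adjusted over the list alone; median 0.75, adjusted p = 6.51e-14), with CDH5 and FLI1, a transcription factor of endothelial cells, at 1.14 ± 0.12. TGF-beta genes had 12 rises and 0 falls of 30 (20 and 1 adjusted over the list alone; median 0.82, adjusted p = 1.9e-13), with PMEPA1, a feedback inhibitor of that pathway, at 2.99 ± 0.28. NRF2 genes had 0 rises and 9 falls of 24 (0 and 15 adjusted over the list alone; median −0.51, adjusted p = 1.07e-09), with TXNRD1 at −1.18 ± 0.13. Vasoactive and coagulation genes had 10 rises and 1 fall of 22 (11 and 2 adjusted over the list alone; median 0.47, adjusted p = 8.22e-06), with EDN1 at 1.53 ± 0.12 and 325 ± 17.3 CPM. Each of these 6 lists had an adjusted p of 0.0499 with an estimated correlation. With all replicates 2 of them turned, the stromal list to a median of −2.98 (adjusted p = 0.0651), with COL1A1 at −4.35, and the TGF-beta list to −0.33 (adjusted p = 0.847).

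The call of 12 further lists in replicates 2 to 4 was lost with an estimated correlation. Immediate early genes had 11 rises and 1 fall of 21 (12 and 1 adjusted over the list alone; adjusted p = 8.68e-09), with FOS at 4.29 ± 0.52. Angiogenic sprouting genes had 15 rises and 2 falls of 29 (19 and 3; adjusted p = 1e-08), and Notch pathway genes 6 rises and 0 falls of 19 (8 and 0; adjusted p = 2.71e-06), each with an adjusted p = 0.199 with an estimated correlation. Smooth muscle genes had 7 rises and 1 fall of 14 (adjusted p = 1.39e-05, and adjusted p = 0.104 with an estimated correlation), with the actin-binding TAGLN at 2.21 ± 0.31. Basement membrane genes had 7 rises and 1 fall of 23 (adjusted p = 2.45e-05, and adjusted p = 0.306 with an estimated correlation). NF-kB genes had 7 rises and 3 falls of 22 (adjusted p = 0.00144, and adjusted p = 0.258 with an estimated correlation), with ICAM1, a leukocyte adhesion receptor, at 1.88 ± 0.21. Integrin and focal adhesion genes had 8 rises and 0 falls of 30 (adjusted p = 0.0194, and adjusted p = 0.616 with an estimated correlation). The p53 targets had 7 rises and 0 falls of 29, and epithelial genes 3 rises and 0 falls of 11. Both had an adjusted p of 0.0265, and 0.492 and 0.368 with an estimated correlation. Lower values were found for nuclear oxidative phosphorylation, ribosomal proteins and cell cycle genes. Their adjusted p was 0.000505, 0.0115 and 0.0352, and 0.641, 0.771 and 0.627 with an estimated correlation. With all replicates 6 of the 12 turned. Oxidative phosphorylation and ribosomal genes were higher (medians 0.91 and 1.29, adjusted p = 0.000846 and 2.6e-06). With an estimated correlation the adjusted p was 0.901 and 0.845. Smooth muscle genes had a median of −0.99 (adjusted p = 0.464) with TAGLN at −4.15, NF-kB genes −0.21 (adjusted p = 0.778), integrin genes −0.35 (adjusted p = 0.0738) and basement membrane genes a mean of −0.32 (adjusted p = 0.847).

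The remaining 10 lists did not pass in replicates 2 to 4. The unfolded protein response had an adjusted p of 0.0505, or 0.041 with the replicate block. The adjusted p was 0.174 for the integrated stress response, 0.25 for YAP targets and for the mitochondrial genome, 0.303 for cholesterol biosynthesis, 0.435 for histones, 0.64 for secretory factors (12 rises and 6 falls), 0.641 for adipocyte genes, 0.707 for haematopoietic genes and 0.794 for hypoxia and glycolysis. With all replicates YAP targets were lower (median −0.48, adjusted p = 0.000363, and adjusted p = 0.826 with an estimated correlation).

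The test called 1716 genes for young co-culture against control in replicates 2 to 4, 1190 higher and 526 lower, and 45 with all replicates, 35 higher and 10 lower. Scaling on the endothelial list, which shifted the median of all genes by −0.76, gave 10986 genes, 356 higher and 10630 lower, in replicates 2 to 4, and with all replicates 5807, 49 higher and 5758 lower, with a shift of −0.92. The list medians above are on the TMM scale. On the endothelial-list scale each lies lower by about the −0.76 of those libraries, so a list with a smaller rise lies below 0 there. The count in replicates 2 to 4 was 888 without co-culture replicate 2, 909 without control replicate 4 and 885 without co-culture replicate 4. The all-replicate count was 217 without control replicate 1 and 623 without co-culture replicate 1. It was 5 without control replicate 2 or 3, 0 without control replicate 4, and 1, 3 and 4 without co-culture replicates 2, 3 and 4. DESeq2 called 447 with all replicates. The interferon list then had 3 rises and 0 falls (adjusted p = 3.29e-12, and adjusted p = 0.198 with an estimated correlation).

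Co-culture with senescent MSCs was set against control too. COL1A1 rose in replicates 2 to 4 from 5.83 ± 0.34 to 140 ± 26.1 CPM (SD, n = 3 and 3; log2 fold change 4.60 ± 0.20, adjusted p = 5.98e-07), and COL3A1 from 3.15 ± 0.52 to 50.6 ± 7.97 CPM (4.02 ± 0.23, adjusted p = 4.29e-06). IL1B rose by 3.36 ± 0.22 (adjusted p = 8.12e-06), the cytokine IL6 by 2.73 ± 0.24 (adjusted p = 4.41e-05), HES1 by 3.62 ± 0.24 to 59.8 ± 10.7 CPM (adjusted p = 8.12e-06) and CDH5 by 1.51 ± 0.18 to 711 ± 55.6 CPM (adjusted p = 0.000292). RELN fell by 3.93 ± 0.21 (adjusted p = 1.91e-06) and SERPINB2 by 2.95 ± 0.19 (adjusted p = 8.12e-06). With all replicates COL1A1 stood at −2.93 ± 1.99, COL3A1 at −2.21 ± 1.73 and IL1B at −0.60 ± 1.25, opposite in sign and not past the threshold, and the stromal list had a median of −2.04 (adjusted p = 0.965). Past the threshold there, ALDH1A1 rose by 2.26 ± 0.32 (adjusted p = 0.0292) and PCDH1 by 1.95 ± 0.23 (adjusted p = 0.0123), while RELN fell by 3.64 ± 0.52 (adjusted p = 0.0292) and MAP3K7CL by 2.41 ± 0.28 (adjusted p = 0.0123).

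Stromal genes in replicates 2 to 4 of that comparison had 22 rises and 1 fall of 34 (28 and 1 adjusted over the list alone; median 1.81, adjusted p = 5.94e-58, and 0.0126 with an estimated correlation), with a stromal share of 0.308 to 0.319% of counts. Endothelial identity genes had 17 rises and 0 falls (22 and 0 adjusted over the list alone; median 0.89, adjusted p = 7.8e-17, and adjusted p = 0.0556 with an estimated correlation). TGF-beta genes had 13 rises and 0 falls (18 and 1 adjusted over the list alone; median 1.05, adjusted p = 2.06e-16, and adjusted p = 0.0556 with an estimated correlation). Secretory factor genes had 23 rises and 5 falls of 38 (25 and 6 adjusted over the list alone; median 0.93, adjusted p = 1.56e-10, and adjusted p = 0.068 with an estimated correlation). Interferon genes had 13 rises and 0 falls (16 and 0 adjusted over the list alone; median 0.39, adjusted p = 1.93e-09, and adjusted p = 0.162 with an estimated correlation). NRF2 genes had 0 rises and 9 falls (0 and 14 adjusted over the list alone; median −0.50, adjusted p = 2.99e-10, and adjusted p = 0.0556 with an estimated correlation). Notch pathway genes had 5 rises and 0 falls (8 and 0 adjusted over the list alone; adjusted p = 4.9e-09, and adjusted p = 0.129 with an estimated correlation). Smooth muscle genes had 8 rises and 0 falls (adjusted p = 2.99e-06, and adjusted p = 0.0956 with an estimated correlation). With all replicates smooth muscle genes turned, to a median of −1.21 (adjusted p = 0.416), and TGF-beta genes had a median of −0.17.

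The test called 1428 genes for senescent co-culture against control in replicates 2 to 4, 1032 higher and 396 lower, and 30 with all replicates, 22 higher and 8 lower. Endothelial-list scaling gave 12950 genes, 381 higher and 12569 lower, with a shift of −0.87, and with all replicates 3991, 17 higher and 3974 lower, with a shift of −0.96. List medians of that comparison in replicates 2 to 4 lie lower by about the −0.87 on that scale. The count in replicates 2 to 4 was 2148 without control replicate 2, 874 without control replicate 4, and 788 and 782 without co-culture replicates 2 and 3. The all-replicate count was 263 without control replicate 1, 5, 11 and 1 without control replicates 2, 3 and 4, 0 without co-culture replicate 2 or 3 and 1 without co-culture replicate 4.

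**Figure D4:**
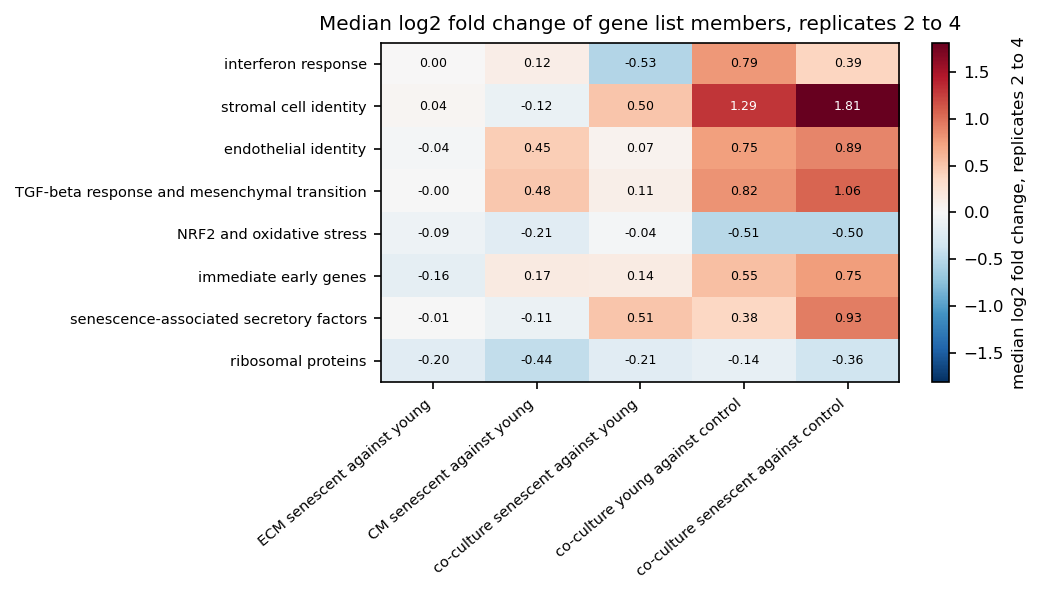
Median log2 fold change of the members of 8 lists in 5 comparisons, replicates 2 to 4, with red above 0 and blue below 0. The interferon list is at −0.53 for senescent against young co-culture and at 0.79 for young co-culture against control.

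Matrix and medium were set against each other over both MSC states, with 8 libraries each. On ECM, SERPINB2 was higher by 3.48 ± 0.42 on the log2 scale (adjusted p = 0.00033), WNT16 by 3.30 ± 0.43 (adjusted p = 0.000503) and AREG by 2.66 ± 0.22 (adjusted p = 1e-05). ABI3BP, a matrix-binding protein, was higher by 2.44 ± 0.30 (adjusted p = 0.000337) and NOS3 by 1.89 ± 0.33 (adjusted p = 0.00322). KRT7 was lower on ECM at −1.81 ± 0.21 (adjusted p = 0.000285), PDGFB, a growth factor for mural cells, at −1.62 ± 0.26 (adjusted p = 0.00178), SNAI1 at −1.45 ± 0.25 (adjusted p = 0.00339) and DLL4, the Notch ligand of tip cells, at −1.02 ± 0.24 (adjusted p = 0.0246). FOXS1, a forkhead factor, was in replicates 2 to 4 at −4.07 ± 0.23 (adjusted p = 6.05e-08) and SERPINB2 at 3.77 ± 0.18 (adjusted p = 1.42e-08).

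With all replicates, epithelial genes had 0 higher and 4 lower of 12 on ECM (0 and 5 adjusted over the list alone; median −0.53, adjusted p = 8.53e-09, and 0.000525 with an estimated correlation), the lower ones including KRT7 and KRT18, the last with near-identical copies. Their median in replicates 2 to 4 was −0.06 and their mean −0.52 (adjusted p = 7.22e-08, and 0.0153 with an estimated correlation). In the p53 target list 0 were higher and 5 lower (adjusted p = 4.53e-06, and adjusted p = 0.382 with an estimated correlation), and in replicates 2 to 4 0 and 10 (0 and 11 adjusted over the list alone; median −0.24, adjusted p = 7.48e-06, and 0.0153 with an estimated correlation). Secretory factors had 5 higher and 0 lower of 40 (7 and 2 adjusted over the list alone; median 0.35, adjusted p = 0.00028, and adjusted p = 0.53 with an estimated correlation). Cell cycle genes had 0 past the threshold (adjusted p = 0.00028, and adjusted p = 0.62 with an estimated correlation). Those of replicates 2 to 4 had 0 higher and 12 lower of 50 (0 and 22 adjusted over the list alone; median −0.28, adjusted p = 1.35e-07, and adjusted p = 0.343 with an estimated correlation). NRF2 genes had 1 higher and 1 lower (adjusted p = 0.00777, and adjusted p = 0.62 with an estimated correlation). Their counts in replicates 2 to 4 were 9 and 0 (12 and 1 adjusted over the list alone; median 0.36, adjusted p = 2.73e-06, and adjusted p = 0.0624 with an estimated correlation). Cholesterol genes had 0 higher and 1 lower (0 and 2 adjusted over the list alone; adjusted p = 0.00112, and adjusted p = 0.62 with an estimated correlation).

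The test called 693 genes for ECM against CM, 377 higher and 316 lower, and 2127 in replicates 2 to 4, 1223 higher and 904 lower. The 693 became 414, 424, 452, 394 and 460 without young ECM replicate 2, senescent ECM replicate 2, senescent ECM replicate 3, young ECM replicate 4 and senescent ECM replicate 4, and 453 and 369 without senescent CM replicates 3 and 4. In replicates 2 to 4 it was 3414 without young ECM replicate 3.

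**Figure D5:**
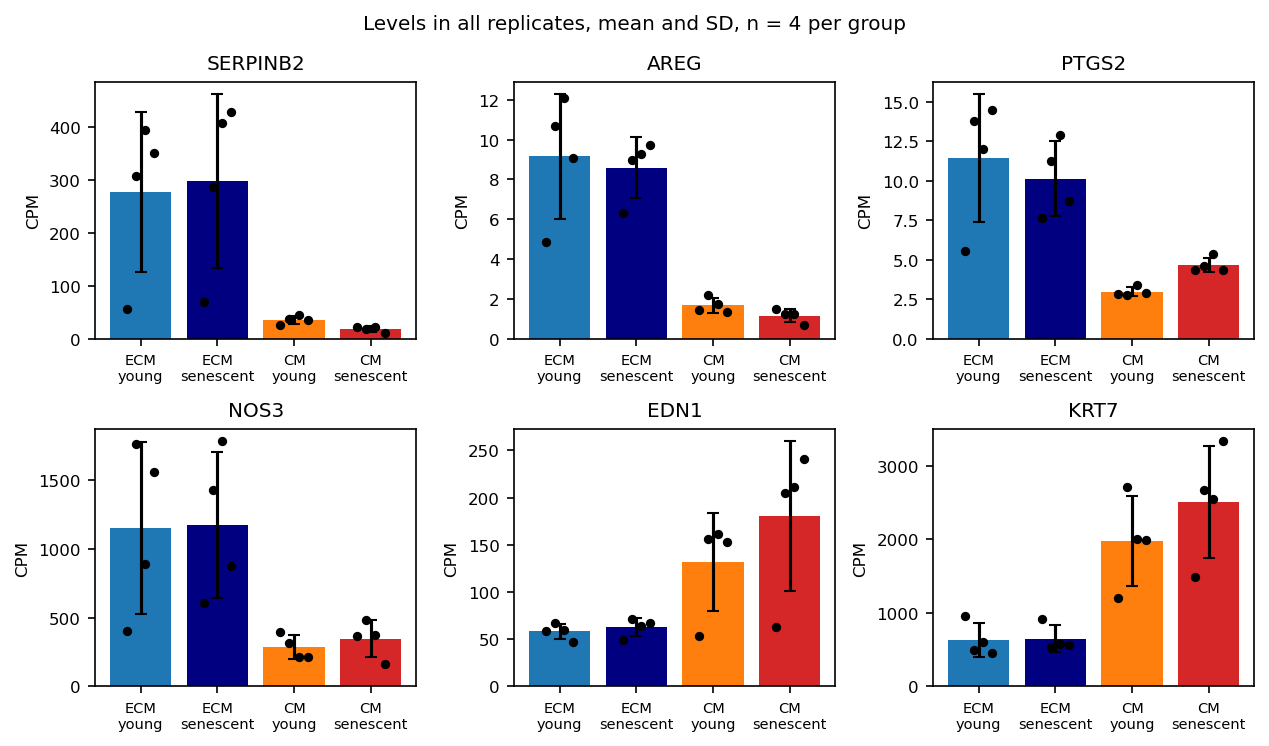
Level (CPM) of 6 genes in the ECM and CM groups, all replicates; bars are means, error bars SDs and points libraries, with n = 4 per group. SERPINB2, AREG, PTGS2 and NOS3 average higher on ECM, and EDN1 and KRT7 higher in CM.

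Whether the effect of senescence differed between ways of exposure was tested as a difference of differences. The effect in co-culture exceeded, in replicates 2 to 4, that in CM for MEDAG by 3.31 ± 0.46 on the log2 scale (adjusted p = 0.00473), EREG by 3.50 ± 0.51 (adjusted p = 0.00533), IL1B by 2.84 ± 0.41 (adjusted p = 0.00533) and C3, complement component 3, by 2.37 ± 0.44 (adjusted p = 0.0332). It lay below that in CM for XAF1 at −2.28 ± 0.31 (adjusted p = 0.00398), OAS2 at −1.65 ± 0.25 (adjusted p = 0.00603) and NEDD9 at −1.14 ± 0.19 (adjusted p = 0.015). Interferon genes had 0 above and 3 below (0 and 13 adjusted over the list alone; median −0.65, adjusted p = 9.44e-26, and 0.00574 with an estimated correlation). Secretory factors had 4 above and 0 below of 40 (13 and 0 adjusted over the list alone; median 0.56, adjusted p = 2.03e-15, and adjusted p = 0.075 with an estimated correlation). Against ECM, the effect in co-culture was larger for MEDAG by 2.96 ± 0.47 (adjusted p = 0.0126), IL1B by 2.62 ± 0.40 (adjusted p = 0.0126), NOTCH3 by 2.45 ± 0.35 (adjusted p = 0.0101) and MMP3 by 2.75 ± 0.44 (adjusted p = 0.0135). The interferon list had a median of −0.53 there (0 and 7 adjusted over the list alone; adjusted p = 2.81e-23, and 0.00742 with an estimated correlation), the secretory list 0.61 (adjusted p = 4.22e-19, and 0.0234 with an estimated correlation) and the cholesterol list −0.37 (adjusted p = 1.12e-10, and 0.00742 with an estimated correlation). Between ECM and CM, TGF-beta and endothelial identity genes had medians of −0.47 and −0.43, each with 0 genes past the threshold. Their adjusted p was 4.2e-09 and 3e-08, and 0.332 and 0.426 with an estimated correlation.

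These tests called in replicates 2 to 4 19 genes for co-culture against CM (13 above, 6 below), 9 for co-culture against ECM (7 and 2) and 0 for ECM against CM, where 384 had an unadjusted p under 0.05 and DESeq2 called 1. Endothelial-list scaling gave 14 for co-culture against CM (13 above, 1 below) and 0 for co-culture against ECM, and XAF1, OAS2 and NEDD9 no longer passed under it (adjusted p = 0.13, 0.297 and 0.172). The 19 became 12 without young or senescent co-culture replicate 2, 11 without young co-culture replicate 4 and 42 without young CM replicate 4. The 9 became 1 without senescent co-culture replicate 2 or senescent ECM replicate 4 and 3 without young co-culture replicate 4, and the 0 became 1 without young ECM replicate 3. With all replicates edgeR called 0 genes in each, with 516, 555 and 124 at an unadjusted p under 0.05 for co-culture against CM, co-culture against ECM and ECM against CM, and DESeq2 called 1, 1 and 0. A count of 1 followed without young CM replicate 4 for co-culture against CM, and without young co-culture replicate 2 or young ECM replicate 3 for co-culture against ECM.

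The fold changes of senescent against young MSCs were compared between ways of exposure across genes, which are not independent replicates. With all replicates Pearson's r was 0.098 between ECM and CM (Spearman's rho 0.19, 18714 genes), 0.142 between ECM and co-culture (0.239, 17711 genes) and 0.27 between CM and co-culture (0.33). For replicates 2 to 4 it was 0.154, −0.006 and 0.021. Among genes with a mean of at least 10 CPM, r was 0.356, 0.433 and 0.467 with all replicates. Single libraries moved r both ways. Without young ECM replicate 3 the first was −0.158 and the next −0.265. Without senescent ECM replicate 1 they were −0.02 and −0.094 (rho 0.022 and 0.207). Without senescent CM replicate 1 the first was 0.001 (0.126). Without young ECM replicate 4 they became 0.167 and 0.264. The first was 0.055, 0.064, 0.051 and 0.047 without young ECM replicate 1, senescent ECM replicate 2, and young CM replicates 2 and 3. The next was 0.224, 0.044 and 0.053 without young ECM replicate 2, senescent ECM replicate 2 and young co-culture replicate 1. For CM and co-culture r was −0.023 (rho 0.334) without senescent CM replicate 1 and 0.062 (0.076) without young co-culture replicate 1. It was 0.122, 0.161 and 0.166 without young CM replicates 2 and 3 and senescent CM replicate 2.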

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

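The tests of induction by the exposure, of co-culture libraries under other labels and of MSC RNA in the co-culture libraries were chosen only after the results were seen. The tests of a single RNA source, of transcript length and of a few dominant genes were written before their own results. They too concern patterns already seen in the data. Of 108 sets of 4 libraries, 29 held a library far from the other 3 by Dixon's test at its 95% limit, where chance gives about 1 in 20.

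Stromal measures held 15 of these, all in replicate 1. The stromal list share was 1.48% in control, 0.913 and 1.01% on young and senescent ECM, and 1.24 and 1.41% in young and senescent CM. Of the list's 38 members 21 were also expressed at a mean of at least 1 CPM in control replicates 2 to 4. COL1A1 was at 4120, 1870, 2190, 4340 and 5000 CPM and TERT at 647, 959, 1220, 765 and 661 CPM in the same order.

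Induction by the MSC exposure was argued against by control replicate 1, which had no exposure and stood 9.3 above the highest other control for COL1A1 on the log2 scale. The co-culture libraries of this series under other labels were argued against by the lowest COL1A1 level of the 5, which lay 3.37 above the highest in any co-culture library, but the 273 genes lower in both co-culture groups had medians of −0.70, −0.71, −0.63, −0.38 and −0.17 in the 5 libraries, up to 0.67 of the −1.06 in co-culture, so a co-culture with a larger share of MSCs stays open. RNA of another cell type from a single source predicted 1 ratio between stromal genes, and the lowest correlation of log2 excess between 2 of the 5 libraries was 0.948 across 27 of the 38 stromal list members with an excess above 1 CPM in each. That correlation spans genes of unlike level and is a weak test of 1 ratio. COL1A1 went from 1870 CPM on young ECM to 5000 CPM in senescent CM, while THY1 went from 388 to 488 CPM. TERT was highest on ECM, at 959 and 1220 CPM, where COL1A1 was lowest. A source of fixed composition was therefore not shown. THY1 and POSTN, abundant in stromal cells, stood at 388 to 488 and 319 to 691 CPM against at most 1.73 and 1.5 CPM in the other 15 libraries of these groups, and the endothelial list share was 60.9 to 81.1% of the mean of replicates 2 to 4. A candidate explanation is RNA of the hTERT-immortalised MSC line in these libraries; whether it entered in culture, at extraction or at library preparation was not tested.

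Young co-culture replicate 1 held 6 more of them. Its TMM factor was 0.459 (others 1.059 to 1.074), its ribosomal protein share 16.9% (3.75 to 5.77%), PECAM1 323 CPM (1280 to 1370) without TMM scaling, or 704 CPM (1204 to 1278) with it, and, with TMM scaling, CCM2L 36.8 CPM (14.2 to 16), MPZL2 2.36 CPM (7.05 to 8.3) and FGF5 16.6 CPM (37.7 to 40.4).

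A few genes taking most of the counts were argued against as its cause, since without the 29 genes among the 10 most counted of any library its TMM factor was 0.535 and the lowest of the other 26 libraries 0.943. A loss of long transcripts may contribute, as Spearman's rho across 19121 genes between exonic length and the log2 ratio to the rest of its group was −0.394. That is only somewhat beyond young co-culture replicate 3, at −0.323, a library that did not stand apart. The senescent co-culture group has no replicate 1, so no library of equal number was there to compare, and no biological explanation was tested.

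The remaining 8 lay in single genes, with TMM scaling except for PECAM1. HES1 was at 48.1 CPM in young co-culture replicate 2 (75.4 to 79.8 in the others) and PECAM1 at 228 CPM in senescent ECM replicate 1 (481 to 502). In young ECM replicate 1, SERPINB2 was at 56.2 CPM (307 to 394), WNT16 at 1.79 CPM (10.1 to 10.8) and STC1 at 109 CPM (395 to 499). In senescent ECM replicate 1, WNT16 was at 2.06 CPM (9.45 to 11.3), KRT7 at 917 CPM (535 to 575) and MYLK2 at 13.9 CPM (2.71 to 3.58).

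In replicates 2 to 4, 13 gene values passed a test of the difference in the effect of senescence between ways of exposure. Co-culture minus CM gave 3.31 for MEDAG, 2.84 for IL1B, 2.37 for C3, 2.19 for MOXD1, 2.25 for NOTCH3, 3.50 for EREG, −2.28 for XAF1, −1.65 for OAS2 and −1.14 for NEDD9 on the log2 scale. Co-culture minus ECM gave 2.96 for MEDAG, 2.62 for IL1B, 2.45 for NOTCH3 and 2.75 for MMP3.

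Stromal genes were higher in co-culture than in control and higher with senescent than with young MSCs in replicates 2 to 4. MSC RNA in the co-culture libraries is in line with TERT, whose lowest level in the 6 co-culture libraries lay 0.68 above the highest of 3 controls on the log2 scale, with TMM scaling. A larger share of MSC RNA alone would raise stromal genes and TERT alike. The 19 stromal genes above 3 times control in senescent co-culture had a median of 1.02, from 0.12 to 2.5. They were picked by their level in senescent co-culture, which raises that median, so it gives no firm size for their rise. TERT had −0.84 ± 0.19 (adjusted p = 0.13) with an upper 95% limit of −0.37. The stromal list's share of counts overlapped (0.308 to 0.319% with senescent and 0.262 to 0.36% with young MSCs). TERT per senescent MSC was not measured, so a larger share together with a lower TERT level per cell stays open, as does a change in the MSCs' own expression. Genes such as IL1B, MMP3 and MEDAG may therefore come from the MSCs, the endothelial cells or both.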

How the results depend on the processing

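All results for replicates 2 to 4 were chosen after seeing the data, as was every alternative applied to them, while the other settings were planned. With all replicates, simulated 2-fold changes were recovered at 24% for senescent against young ECM, 0% for co-culture and 58% for ECM against CM. The shares in replicates 2 to 4 were 48, 65 and 79%. Size factors of the DESeq2 type moved no count of genes by over 1.5 times, and no list lost its call with them. Named genes lost their call in 2 values with all replicates and in 2 with replicates 2 to 4 under those size factors. The cause of the changes given here was not tested, except where a setting leaves out libraries or genes.

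From all replicates to replicates 2 to 4 the counts went from 0 to 3 for senescent against young CM, from 0 to 70 for senescent against young co-culture, from 1 to 117, 0 to 54, 0 to 91, 45 to 1716 and 30 to 1428 for young ECM, senescent ECM, senescent CM, young co-culture and senescent co-culture against control, from 693 to 2127 for ECM against CM, and from 0 to 19 and 9 for the senescence effect of co-culture minus CM and minus ECM. DESeq2 gave 1, 4, 32, 32, 38, 447, 216 and 1219 genes for these 8 comparisons of groups with all replicates and 1 for each of the 2 differences. In replicates 2 to 4 it gave 46 and 151 for senescent against young CM and co-culture, 330, 225, 34 and 261 for young ECM, senescent ECM, young CM and senescent CM against control, and 1, 64 and 27 for the differences of ECM minus CM, co-culture minus CM and co-culture minus ECM.

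With all 7 groups in 1 fit the counts were 2 for senescent against young co-culture, 0 for young ECM against control, 402 and 135 for young and senescent co-culture against control, and 417 for ECM against CM. With only the compared groups they were 0 for young ECM, 0 for young co-culture and 150 for senescent co-culture against control. Without a filter they were 0 for young ECM, 24 for young co-culture and 424 for ECM against CM, and a minimum of 50 counts gave 2 for young ECM. Scaling on the endothelial list gave 5807 and 3991 genes for young and senescent co-culture against control with all replicates and 10986 and 12950 in replicates 2 to 4, 29 for senescent against young co-culture, and 0 for co-culture minus ECM. That scaling shifted the median of all genes by −0.11 for senescent against young co-culture in replicates 2 to 4, by 0.28 and 0.27 for co-culture minus CM in both sets, and by −0.16 for co-culture minus ECM.

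The replicate block gave 101 and 123 genes for young and senescent ECM and 84 for senescent CM against control, and in replicates 2 to 4 321 for young ECM, 6 for young CM and 230 for senescent CM. Lists that changed there were the ribosomal list for senescent against young ECM (0.06), the epithelial list for senescent CM (0.0505) and the unfolded protein response for young co-culture in replicates 2 to 4 (0.041), and the block changed no other call where the numbers paired the libraries. Elsewhere not every pair of same-numbered libraries correlated above 0.1, and the block gave 3014 genes for ECM against CM, 2 for co-culture minus CM, and in replicates 2 to 4 7 for senescent against young CM, 200 for senescent ECM against control, 3320 for ECM against CM, 54 for co-culture minus CM and 24 for co-culture minus ECM. With all replicates and the block the secretory list passed for co-culture minus CM (1.7e-07, and 0.0223 with an estimated correlation) and minus ECM (7.61e-08, and 0.00783), against 0.259 and 0.101 without the block (0.987 and 0.779 with an estimated correlation). The stromal list passed for senescent co-culture against control (4.58e-06, and 0.751 with an estimated correlation), where the vasoactive list no longer did (0.175). Of the genes named with all replicates MPZL2, FGF5 and OAS1 for young and ALDH1A1, AMTN and AOX1 for senescent co-culture no longer passed. Pairs there correlated between −0.06 and 0.94 for ECM against CM, 0.03 and 0.86 for senescent against young CM, −0.75 and 0.75 for senescent against young co-culture, −0.05 and 0.38 for young and −0.25 and 0.34 for senescent co-culture against control. Of the libraries with a partner, 14 of 16, 5 of 8, 2 of 6, 3 of 8 and 2 of 6 correlated best with their own number. In replicates 2 to 4 pairs reached from −0.29 to 0.84 for ECM against CM, 0.1 to 0.68 for senescent against young CM and −0.31 to 0.73 for senescent ECM against control.

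Leaving out 1 library with all replicates gave 0 to 0 genes for senescent against young ECM and CM, senescent ECM and young CM against control, and ECM minus CM. It gave 0 to 1 for senescent against young co-culture, co-culture minus CM and co-culture minus ECM, 0 to 16 for young ECM, 0 to 3 for senescent CM, 0 to 623 for young co-culture and 0 to 263 for senescent co-culture against control, and 369 to 942 for ECM against CM. In replicates 2 to 4 the ranges were 0 to 0 for senescent against young ECM, 0 to 2 for CM and 25 to 55 for co-culture. Against control they were 27 to 131 for young ECM, 12 to 36 for senescent ECM, 0 to 2 for young CM, 22 to 74 for senescent CM, 885 to 2339 for young co-culture and 782 to 2148 for senescent co-culture. They were 1492 to 3414 for ECM against CM, 0 to 1 for ECM minus CM, 11 to 42 for co-culture minus CM and 1 to 11 for co-culture minus ECM. Pearson's r of senescence effects spanned −0.158 to 0.167 (ECM and CM), −0.265 to 0.264 (ECM and co-culture) and −0.023 to 0.313 (CM and co-culture). Among genes of at least 10 CPM it was 0.356, 0.433 and 0.467, in replicates 2 to 4 −0.006 for ECM and co-culture and 0.021 for CM and co-culture, and without the stromal list and the 500 genes most changed in co-culture 0.118, 0.145 and 0.278.

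Of the genes named in replicates 2 to 4, 30 values changed sign with all replicates, 189 no longer passed and 36 passed. For young co-culture against control these were COL1A1 −4.35, NID2 −3.76, BIRC5 0.12, ADM 0.00, NUPR1 −3.61, ITGA11 −2.81, NOTCH3 −5.66, MYL9 −4.70, TAGLN −4.15, COL1A2 −4.38, TGFB2 −2.50 and CCN1 −0.06. For senescent co-culture they were COL5A3 −2.86, COL1A1 −2.93, MEDAG −0.27, COL3A1 −2.21, NID2 −2.21, FBLN1 −1.44, IER3 −2.16, NUPR1 −3.58, ITGA11 −3.00, XAF1 −0.50, NOTCH3 −3.39, IL1B −0.60, MYL9 −4.19, TAGLN −4.31, COL1A2 −2.94, F3 −3.81 and TGFB2 −2.59, and for ECM against CM EGR1 −0.58. Endothelial-list scaling turned 9 values of replicates 2 to 4: KDM3A −0.18, PDIA4 −0.20 and HSP90B1 −0.25 for young, and INSIG1 −0.23, KRT7 −0.16, ADM −0.08, GDF15 −0.01, PLK3 −0.05 and PDIA4 −0.28 for senescent co-culture against control.

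Going from all replicates to replicates 2 to 4 turned 10 lists, whose adjusted p in replicates 2 to 4 was 5.02e-29 for stromal, 1.9e-13 for TGF-beta, 1.39e-05 for smooth muscle, 0.00144 for NF-kB, 0.25 for YAP, 2.45e-05 for basement membrane, 0.0194 for integrin, 0.0115 for ribosomal and 0.000505 for oxidative phosphorylation genes in young co-culture, and 2.99e-06 for smooth muscle genes in senescent co-culture against control. Of 79 list results in replicates 2 to 4, 48 lost their call with an estimated correlation and 23 with fry, and 1 gained it with fry. With all replicates 52 and 51 of 79 lost it. The 79 include lists that had no call to lose, so those left are not all calls that held. Single genes lost their call in 336 of the values without 1 library in replicates 2 to 4, where 1590 kept it, and in 230 with all replicates, where 561 kept it. DESeq2 kept the call of all 255 gene values named in replicates 2 to 4 and all 61 named with all replicates.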

Other observations

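The test of MSC RNA as a source of the endothelial list's rise and all results for replicates 2 to 4, their splits included, were chosen only after the data were seen, while the counts of other splits with all replicates were planned.

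DHRS3 and ATOH8 also separated the co-culture groups in replicates 2 to 4. DHRS3, a retinaldehyde reductase induced by retinoic acid (chromosome 1, 12567910 to 12617731 of GRCh38), stood at 0.59 ± 0.12 CPM in control, 6.53 ± 0.43 with young and 1.73 ± 0.46 with senescent MSCs (SD, n = 3 each; senescent against young −1.92 ± 0.22, adjusted p = 0.00318). ATOH8, a helix-loop-helix transcription factor, was at 14.5 ± 3.31, 26.9 ± 3.76 and 11.8 ± 0.84 CPM (−1.19 ± 0.19, adjusted p = 0.0183).

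PLVAP, a protein of endothelial fenestrae, was at 41.3 ± 5.6 CPM with senescent and 19.7 ± 1.78 CPM with young MSCs in co-culture replicates 2 to 4 (1.07 ± 0.18, adjusted p = 0.0326), and TNFAIP3, a feedback inhibitor of NF-kB, at 12.6 ± 1.25 and 6.64 ± 1.23 CPM (0.93 ± 0.17, adjusted p = 0.0423). Both were also higher on ECM than in CM in those replicates, by 1.68 ± 0.21 (adjusted p = 8.88e-05) and 1.43 ± 0.20 (adjusted p = 0.000207).

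Endothelial identity genes were higher in co-culture than in control, with 26 of 30 above 0 with young and 27 with senescent MSCs, in replicates 2 to 4. RNA from added MSCs would lower the share of endothelial transcripts, yet the lower of the 2 medians was 0.75, which argues against MSC RNA as the source of that rise. A hypothesis that remains is a response of the endothelial cells to contact, not separated from effects of a shared culture such as density. Smaller medians above 0 came without cell contact, with all replicates: 0.275 in senescent CM, 0.151 and 0.158 on young and senescent ECM. Young CM had −0.02.

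Other splits of the libraries were counted for each comparison. With all replicates the real split gave 45 genes for young co-culture against control (highest other 8). Its share, 1 of 35, is the lowest possible and was not corrected for the other comparisons, so chance was not firmly excluded. For young ECM against control it gave 1 gene (highest other 0), also 1 of 35, but the numbers pair these libraries, and the 8 splits that part as many pairs are too few for a share under 0.05. For senescent co-culture against control 2 of 35 splits gave at least the 30 genes, the other giving 31 by exchanging all of replicates 2 to 4, so that control replicate 1 stood with the co-culture libraries, and chance was not excluded. With 0 genes, 6 comparisons say nothing about chance, as all 35 splits gave as many (highest other 0). They were senescent against young in each way of exposure, and senescent ECM, young CM and senescent CM against control. For ECM against CM, 6 of 100 splits gave at least 693 genes (highest other 3836), so chance was not excluded there. The split with 3836 put all 4 libraries numbered 1 on the same side, so it follows the replicate structure, and with the replicate number as a block the real split gave 3014. Among splits of replicates 2 to 4, 3 of 100 gave at least 2127 (highest other 3088), a share under 0.05. Of those libraries 9 of 12 correlated best with their own number, while the splits exchange libraries across numbers. The share therefore does not settle whether chance is excluded. Splits with several times the real count point to a structure of the samples beyond the compared groups. For the differences of senescence effects, the real count with all replicates was 0, which 100 of 100 splits must reach, so only the highest others inform: 1411 for ECM against CM, 1 for co-culture against CM and 1033 for co-culture against ECM. Among splits of replicates 2 to 4, 4 of 100 gave at least 19 for co-culture against CM (highest other 63). At least 9 for co-culture against ECM came from 8 of 100 (highest other 47), and for ECM against CM the real count was again 0 (highest other 1910). These splits exchange young and senescent labels within each way of exposure, so a low share can come from 1 way alone. They cannot decide whether the effects differ, and excluded chance for no difference.

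With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest other were 0 and 0 for senescent against young ECM and for young CM against control, where 10 of 10 gave as many. They were 3 and 0 for senescent against young CM, 70 and 0 for senescent against young co-culture, 54 and 0 for senescent ECM, 91 and 0 for senescent CM, 1716 and 1 for young co-culture and 1428 and 0 for senescent co-culture against control, each with 1 of 10. For young ECM against control they were 117 and 1671, with 2 of 10. Where numbers paired the libraries, only splits parting as many pairs were compared, 8 of 35 or 4 of 10. The highest other of them gave 0 genes each time. The rest, which keep some pairs together, gave at most 1671 for young ECM, by exchanging control replicate 2 with ECM replicate 3, at most 1 for young co-culture and 0 elsewhere. That split sorts the libraries by ribosomal share (4.74 to 7.56% against 3.62 to 4.4%) and only in part by replicate number. The structure behind its many calls was not identified.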
